A study of Saccharomyces cerevisiae with 14 samples.

How the data were processed

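Polyadenylated RNA of budding yeast (Saccharomyces cerevisiae) was measured by sequencing in 14 libraries, 2 for each of 7 groups: untreated cells at 0 h, cells given ethanol for 1, 2 or 4 h, and cells given 5 nM beta-estradiol in ethanol for 1, 2 or 4 h. Per the labels' protocols, all cultures grew in synthetic complete medium with 2% glucose, DNase was used on the RNA, and libraries were made from poly-A selected RNA with a Kapa kit. The labels' protocols name an induction of 1 h only, while each sample's own label gives 1, 2 or 4 h; the sample labels were used to form the groups. Per the submitters' processing notes, reads were aligned with Bowtie2 2.2.5. The counting tool, the genome build, and whether reads were counted by strand are not given in the sources used here. The deposited table holds raw read counts per open reading frame, in whole numbers with no normalization, and each library is its own column. Its 6670 identifiers include 0 with no count in any library.

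Gene symbols came from the R64 assembly's gene table, used for names and for which genes neighbour each other: 5999 of the 6670 identifiers matched and 671 did not, and 542 of the latter were among the genes tested. No coordinates are given, since the build behind the counts is not stated.

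Counts were analysed in R 4.3.3 with edgeR 4.0.16. Library sizes were scaled by TMM factors, genes were kept by filterByExpr on the group with its minimum count of 10, and 6337 genes remained. A quasi-likelihood model with robust dispersion and a coefficient for each of the 7 groups was fitted to all 14 libraries, which left 7 residual degrees of freedom and a common biological coefficient of variation of 0.206. Tests were 2-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p under 0.05 were called. Log2 fold changes are given with a standard error (SE), and each group has n = 2. The SE is the absolute log2 fold change divided by the square root of its F statistic. The 95% intervals use this SE with 7 degrees of freedom. Estradiol was compared with ethanol at 1, 2 and 4 h, and every treated group was compared with the untreated one. An average effect came from the 12 treated libraries with time as a factor and 6320 genes. A change of the effect with time came from a joint F test on the 2 h effect minus the 1 h effect and the 4 h effect minus the 1 h effect. Levels are given as TMM-scaled CPM, mean ± SD. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these samples.

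There were 24 gene lists, none of which shared a gene, among them SBF regulon cyclins and regulators, SBF regulon cell wall and bud growth genes, MBF regulon DNA replication and repair genes, core histones, Hcm1 targets of the spindle, the CLB2 cluster, ECB and MCM genes, mating pheromone response, alpha-specific genes, meiosis and sporulation, ribosomal proteins, ribosome biogenesis, Msn2/4 general stress genes, respiratory chain and TCA cycle, glucose-repressed genes, Gcn4 targets of amino acid biosynthesis, sulfur and methionine, galactose genes, pleiotropic drug response, the PHO regulon, cell wall stress and Rlm1 targets, the iron regulon and ergosterol biosynthesis. They were written from general knowledge of these regulons. Each was tested against all other genes with camera (limma 3.58.1) on log2 CPM, with a preset correlation between genes of 0.01 and adjustment over the 24 lists, and again with the correlation estimated for each list. Called members were counted after adjustment over all genes and also adjusted over the list alone. 1 list is not reported here, though it stays in the adjustment and in the counts of lists and named calls. Named genes followed a rule. Always named were SWI4, SWI6, MBP1, WHI5, CLN3, BCK2, STB1, MSA1, MSA2, CLN1, CLN2, PCL1 and PCL2. For estradiol against ethanol, the 6 highest and 6 lowest called genes were added if their average log2 CPM was at least 3 and both estradiol libraries lay beyond both ethanol libraries. For each list with a called member, up to 4 members with the smallest p were added. For ethanol against untreated cells and for the test of the change with time, the 4 highest and 4 lowest were taken by the same filter. The groups, comparisons, tests, lists, naming rule and the first set of other settings were chosen before the data were examined.

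The first set of other settings held size factors by the median of ratios (RLE), library totals alone, no filter on low counts, a mean CPM of at least 10, the replicate number as a block, only the libraries of the groups compared, DESeq2 1.42.0, a mean of the contrasts in place of the additive model, and leaving out each library in turn. Added after the data were seen were a surrogate variable from sva 3.50.0 with the groups protected, removal of a trend on gene length or on GC content from each library, omission of the unmatched identifiers and of reading frames inside the ribosomal DNA, the list tests with the surrogate variable, and the list test on differences between times. A library left alone in its group was assumed to vary like the libraries of the other groups. The surrogate variable was estimated from the same counts and takes up spread within groups. More calls with it are therefore likely, and such calls are not separate evidence for a result. Between estradiol and ethanol it differed by -0.40 at 1 h, -0.010 at 2 h and 0.020 at 4 h.

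The model was tested on simulated counts drawn from each gene's mean over all libraries, its estimated dispersion and the real library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. For estradiol against ethanol at 1 h, with 6323 genes, 31% of the 2-fold and 97% of the 4-fold changes were recovered and 7.25% of the calls were false. At 2 h, with 6323 genes, the shares were 41%, 97% and 9.21%. At 4 h, with 6321 genes, they were 40%, 98% and 4.17%. For the average over the times, with 6301 genes, they were 97%, 100% and 5.74%. The changed genes were drawn only from those above a floor of mean CPM, so recovery at lower counts was not measured. Simulated genes were independent of each other. Spread shared between genes was therefore not simulated, and the share of false calls in the real data may differ.

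Total counts per library ran from 3.47 M to 17.3 M. A floor of 3 counts corresponds to 1.13 CPM in the shallowest library by scaled size, ethanol 1 h replicate 1, and to 0.158 CPM in untreated replicate 2. Such a floor covers counting error only, and PCR duplicates cannot be recognised in a table of counts. Sequence reads were not analysed here.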

Results

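The series asks how the transcripts of budding yeast respond when SWI4 is induced. SWI4 encodes the DNA-binding subunit of SBF, the transcription factor that turns on cyclin genes in late G1. The genotype label, Z3EVpr-SWI4, names a promoter driven by an estradiol-activated synthetic transcription factor. The 14 libraries formed 7 groups of 2: untreated cells, cells mock-induced with ethanol for 1, 2 or 4 h, and cells induced with estradiol for 1, 2 or 4 h. Total counts in replicates 1 and 2 were 12.3 M and 17.3 M in untreated cells. They were 3.70 M and 4.69 M at 1 h, 3.47 M and 5.70 M at 2 h and 12.3 M and 16.2 M at 4 h of ethanol. With estradiol they were 7.63 M and 8.03 M at 1 h, 6.82 M and 8.68 M at 2 h and 13.2 M and 15.6 M at 4 h. The 10 most abundant genes held 11.1% to 23.3% of a library's counts, and Pearson correlations of log2 CPM within the pairs ran from 0.957 to 0.993.

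SWI4 (YER111C) separated the induced from the other libraries without overlap. Its level was 19.3 ± 1.99 CPM (SD, n = 2) in untreated cells and 13.6 ± 2.06, 15.6 ± 0.112 and 17.5 ± 7.70 CPM after 1, 2 and 4 h of ethanol. With estradiol it was 1369 ± 511, 1156 ± 351 and 859 ± 269 CPM. Against ethanol of the same time this was 99.98-fold at 1 h (95% interval 45.7 to 219), 74.2-fold at 2 h (34.6 to 159) and 49.0-fold at 4 h (23.6 to 102). The adjusted p-values were 2.28e-05, 3.59e-05 and 5.52e-05. The counts do not separate transcripts of the induced copy from those of any native copy.

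**Figure D1:**
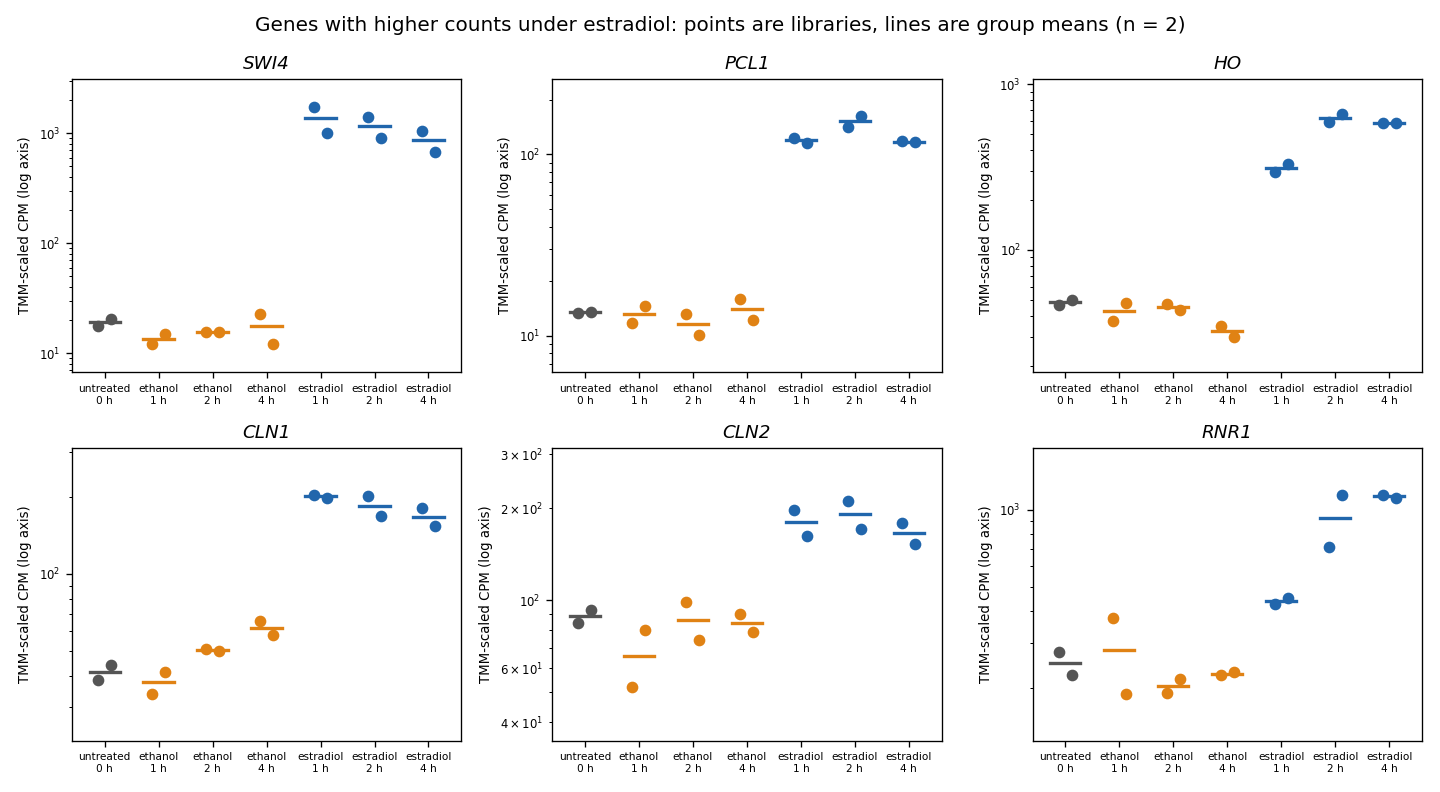
TMM-scaled CPM on a log axis for 6 genes in the 7 groups; each point is a library and each line the mean of a group (n = 2). SWI4 lay at 859 to 1369 CPM on average in the estradiol groups and at 13.6 to 19.3 CPM in the others.

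The comparison of estradiol with ethanol at 1 h asks what differs at the earliest time sampled. No group lacks the induced SWI4 construct. Effects of SWI4 therefore cannot be told apart from other effects of estradiol or of the factor it activates. PCL1 (YNL289W), a cyclin of the Pho85 kinase, rose by 3.16 on the log2 scale (SE 0.22, n = 2, adjusted p = 2.06e-05). CLN1 (YMR199W) and CLN2 (YPL256C), G1 cyclins of Cdc28, rose by 2.41 (SE 0.19) and 1.44 (SE 0.24). HO (YDL227C), the mating-type switching endonuclease and a classic SBF target, rose by 2.87 (SE 0.21). The gene that fell most was MFA1 (YDR461W), which encodes the a-factor pheromone, at -4.78 (SE 0.28, adjusted p = 9.08e-06), from 75.0 ± 4.07 to 2.70 ± 0.256 CPM.

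Of the 9 SBF regulon cyclins and regulators, 5 rose and 0 fell, with a median of 1.44 (7 and 0 adjusted over the list alone); the list test gave an adjusted p of 6.20e-16, and 0.0136 with an estimated correlation. YHP1 (YDR451C), a homeodomain repressor, rose by 1.52 (SE 0.19), and PCL2 (YDL127W) stood at 0.73 with an adjusted p of 0.0602. Of the 20 SBF regulon cell wall and bud growth genes, 3 rose: TOS6 (YNL300W) by 2.09, MNN1 (YER001W), a mannosyltransferase, by 1.57 and CSI2 (YOL007C) by 1.54. Adjusted over the list alone, 9 rose and 1 fell; the list test gave 1.79e-06, and an adjusted p of 0.206 with an estimated correlation. The 32 MBF regulon DNA replication and repair genes went both ways: the S-phase cyclin CLB5 (YPR120C) rose by 1.68 and NRM1 (YNR009W), a co-repressor of MBF, by 1.69, while the thymidylate synthase gene CDC21 (YOR074C) fell (-1.29), as did the DNA ligase gene CDC9 (YDL164C; -1.05). Adjusted over the list alone, 4 of them rose and 9 fell; the median was -0.43, the list test gave a lower direction with an adjusted p of 0.00316, and adjusted p = 0.40 with an estimated correlation. With the surrogate variable 5 MBF genes were called higher and 17 lower.

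Of the 20 mating pheromone response genes, 0 rose and 3 fell, 13 adjusted over the list alone. The agglutinin genes AGA1 (YNR044W) and AGA2 (YGL032C) fell (-2.51 and -1.46); the list test gave 1.29e-07, and 0.0111 with an estimated correlation. PRM6 (YML047C) also passed, at 0.0600 against 1.35 CPM, with a lowest count of 0, so no fold is given. The other a-factor gene, MFA2 (YNL145W), is outside that list and fell (-2.64, SE 0.30).

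The 8 ECB and MCM genes held 2 that fell, the replicative helicase genes MCM7 (YBR202W) at -1.46 and MCM5 (YLR274W) at -1.02, and 0 that rose. Adjusted over the list alone, 5 fell and 1 rose; the list test gave 5.11e-05, and an adjusted p of 0.166 with an estimated correlation. Of the 18 CLB2 cluster genes, the mitotic cyclin gene CLB1 (YGR108W) rose by 1.71, 7 rose adjusted over the list alone and the median was 0.80; the list test gave 3.07e-07, and an adjusted p of 0.284 with an estimated correlation. Of the 14 PHO regulon genes, the phosphate transporter gene PHO89 (YBR296C; -2.47) and the acid phosphatase gene PHO5 (YBR093C; -1.92) fell (3 fell adjusted over the list alone; adjusted p = 2.60e-05, and 0.235 with an estimated correlation). Of the 15 iron regulon genes, the siderophore transporter gene SIT1 (YEL065W) fell (-1.82) (7 fell adjusted over the list alone; adjusted p = 3.13e-05, and 0.166 with an estimated correlation). All 32 Gcn4 targets had negative values with 0 called, 7 adjusted over the list alone, and a median of -0.68 (adjusted p = 3.13e-10, and 0.364 with an estimated correlation). With the surrogate variable the medians at 1 h were smaller: -0.21 for Gcn4 targets, -0.26 against -0.62 for the PHO genes, -0.33 against -0.72 for the iron genes and 0.39 against 0.80 for the CLB2 cluster. Calls were then 6 lower for Gcn4 targets, 2 higher and 5 lower for the iron genes, and 4 higher for the CLB2 cluster. There were 11 higher and 1 lower for the SBF cell wall genes, 9 lower for the pheromone response and 5 lower for the ECB and MCM genes. In ethanol at 1 h against untreated cells, medians were 0.34 for Gcn4 targets, 0.48 for PHO genes and -0.30 for the CLB2 cluster. The list tests gave adjusted p-values of 0.0111, 0.000167 and 0.0202, and 0.782, 0.505 and 0.746 with an estimated correlation. Iron genes stood at 0.21 and ECB and MCM genes at -0.19, neither past the test. Part of the 1 h differences of Gcn4, PHO and CLB2 genes may therefore lie in the ethanol libraries.

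Ribosomal protein genes, 0 of 132 called, had a median of -0.21, which scaling by library totals turned to 0.11 (adjusted p = 3.07e-05, and 0.873 with an estimated correlation). Of 19 ergosterol genes 0 were called, at a median of -0.39 that the same scaling moved to 0.0012 (adjusted p = 0.00316, and 0.805 with an estimated correlation). Their median in ethanol at 1 h against untreated cells was 0.31 (list test adjusted p = 0.00718, and 0.746 with an estimated correlation). The 12 other lists did not pass: among them the single called members were SPS4 (YOR313C) of the meiosis list, which rose by 2.35, and YGP1 (YNL160W) of the stress list, a cell wall glycoprotein gene, which fell (-1.93). Their adjusted p-values ran from 0.0875 for meiosis and sporulation to 0.971 for core histones. Other genes named by the rule were RNR2 (YJL026W), the small subunit gene of ribonucleotide reductase, which rose by 2.49 (SE 0.51, adjusted p = 0.0455; this call and that of PHO5 were lost with the replicate number as a block), TIP1 (YBR067C), a cell wall mannoprotein gene, at -3.10, and the acid phosphatase gene PHO3 (YBR092C) at -2.56. YJL026C-A, at 2.37, lies by its name beside RNR2 on the opposite strand; whether reads were counted by strand is not given in the sources used here, so it is not treated as a separate gene. Of the regulators of SBF and MBF, MSA2 (YKR077W) fell (-1.11, adjusted p = 0.0354). SWI6 (YLR182W) stood at 0.71 (adjusted p = 0.557), MBP1 (YDL056W) at 0.90 (0.540), WHI5 (YOR083W) at -1.53 (0.0993), CLN3 (YAL040C) at -0.28 (0.567), BCK2 (YER167W) at 0.45 (0.572), STB1 (YNL309W) at -0.85 (0.467) and MSA1 (YOR066W) at -1.09 (0.0554).

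In all, 61 of 6337 genes were called at 1 h, 30 higher and 31 lower, and 59 of them differed by more than 2-fold; 616 genes had an unadjusted p under 0.05. The count was 25 without ethanol 1 h replicate 1, 205 without ethanol 1 h replicate 2, 12 without estradiol 1 h replicate 1 and 17 without estradiol 1 h replicate 2, and 10 of the 36 named calls were kept whichever library was left out: SWI4, CLN1, PCL1, HO, MFA1, MFA2, YHP1, CSI2, CLB5 and PHO89. With library totals as the only scaling, the median of all genes moved by 0.31, the calls were 37 higher and 19 lower, and 21 of the 36 named calls were kept, CLN2 not among them (adjusted p = 0.270); DESeq2 called 60 higher and 97 lower.

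At 2 h of estradiol against 2 h of ethanol, the same question was asked of a later time. HO rose by 3.79 (SE 0.22, n = 2) and PCL1 by 3.71 (SE 0.22), each with an adjusted p of 3.83e-06, and CLN1 rose by 1.89 (SE 0.19) and CLN2 by 1.15 (SE 0.24). The call of CLN2 was lost with the replicate number as a block and with library totals (adjusted p = 0.893). RNR2 rose by 3.88 (SE 0.54) and RNR1 (YER070W), the large subunit gene of ribonucleotide reductase, by 2.19 (SE 0.33). TIR1 (YER011W), a cell wall mannoprotein gene, rose by 4.48 (SE 0.65), from 2.16 ± 1.27 to 50.7 ± 41.4 CPM. MFA1 (-4.09, SE 0.27), TIP1 (-2.72), PHO3 (-2.54), MFA2 (-2.33) and YRO2 (YBR054W; -2.32) fell.

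Of the 9 SBF regulon cyclins and regulators, 5 rose and 0 fell, 8 and 0 adjusted over the list alone (median 1.15, adjusted p = 4.16e-24, and 0.00778 with an estimated correlation); YHP1 rose by 1.73. Of the 20 SBF regulon cell wall genes, 9 rose and 0 fell, 13 and 1 adjusted over the list alone (median 0.89, adjusted p = 2.35e-20, and 0.0184 with an estimated correlation). Examples were TOS6 at 2.90, SVS1 (YPL163C) at 2.26, CSI2 at 2.00 and MNN1 at 1.70. Of the 32 MBF regulon genes, 5 rose and 1 fell, 6 and 5 adjusted over the list alone. The S-phase cyclin genes CLB6 (YGR109C) and CLB5 rose by 2.42 and 1.72, NRM1 rose by 1.90, and CDC21 fell (-0.91); the list's median was -0.33 and its mean 0.11, and the list test, in the lower direction, gave 0.460. With the surrogate variable 7 MBF genes were called higher and 12 lower.

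The 8 core histone genes had 0 calls over all genes and 2 higher adjusted over the list alone. All 8 values were positive, with a median of 0.56 (list test adjusted p = 7.91e-08, and 0.119 with an estimated correlation). With the surrogate variable all 8 were called higher at the same median of 0.56. Of the ECB and MCM genes 3 fell, MCM7 (-1.42), MCM5 (-1.38) and MCM4 (YPR019W; -0.81), and 6 fell and 1 rose adjusted over the list alone (adjusted p = 6.16e-07, and 0.0595 with an estimated correlation). Of the mating pheromone response genes 0 were called and 4 fell adjusted over the list alone (median -0.37, adjusted p = 1.07e-06, and 0.00995 with an estimated correlation). PHO89 (-2.37) and SPL2 (YHR136C; -1.57) fell among the PHO genes (3 fell adjusted over the list alone; adjusted p = 4.26e-09, and 0.0814 with an estimated correlation). SIT1 fell (-2.04) among the iron genes (4 fell and 1 rose adjusted over the list alone; adjusted p = 1.96e-05, and 0.106 with an estimated correlation).

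The CLB2 cluster had 0 calls and a median of 0.41 (adjusted p = 0.000454, and 0.415 with an estimated correlation). CWP1 (YKL096W), a cell wall mannoprotein gene, rose by 2.90 among the 14 Rlm1 genes (2 rose adjusted over the list alone, list test adjusted p = 0.0218, and 0.351 with an estimated correlation). Its call was lost with only the groups compared. Sulfur and methionine genes had 0 of 17 calls, 1 higher adjusted over the list alone and a median of 0.38 (adjusted p = 0.000189, and 0.194 with an estimated correlation). Among the 22 stress genes YGP1 fell (-2.25), 2 fell and 1 rose adjusted over the list alone, and the median was 0.27 (adjusted p = 0.0485, and 0.774 with an estimated correlation). Gcn4 targets had 0 calls and a median of -0.065 (adjusted p = 0.00468, and 0.774 with an estimated correlation). The other 11 lists did not pass, with the drug response list split between a median of -0.02 and a mean of 0.071, SPS4 at 2.24 being their called member beside those of the MBF list. Calls with the surrogate variable were 6 higher for the CLB2 cluster, 1 higher and 9 lower for Gcn4 targets, and 7 lower for the PHO genes. Stress genes had 5 higher and 2 lower. There were also 2 higher and 5 lower for the iron genes, 5 lower for the pheromone response and 1 higher and 6 lower for the ECB and MCM genes. The other counts were 14 higher for the SBF cell wall genes, 3 higher and 1 lower for the Rlm1 genes and 3 higher for the sulfur genes. Of the regulators, MSA1 fell (-1.15, adjusted p = 0.0355), and WHI5 stood at -1.04 (0.492), MSA2 at -0.87 (0.0912), PCL2 at 0.67 (0.0775), SWI6 at 0.26, MBP1 at 0.49, CLN3 at -0.13, BCK2 at -0.26 and STB1 at -0.11, the last 5 with adjusted p-values that rounded to 1.

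At 2 h 80 genes were called, 57 higher and 23 lower, 72 of them beyond 2-fold, and 405 had an unadjusted p under 0.05. The count was 29 without ethanol 2 h replicate 1 and 29 without ethanol 2 h replicate 2, and 14 of the 33 named calls were kept whichever library was left out, among them SWI4, CLN1, PCL1, HO, MFA1, MFA2, YHP1, CSI2, MNN1 and YGP1. With library totals as the only scaling, 52 were higher and 35 lower, and CLN1 had an adjusted p of 0.0694.

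At 4 h of estradiol against 4 h of ethanol, HO rose by 4.17 (SE 0.22, n = 2, adjusted p = 2.17e-06), from 32.4 ± 3.61 to 581 ± 3.10 CPM. PCL1 rose by 3.06 (SE 0.20), RNR2 by 3.88 (SE 0.54), RNR1 by 2.31 (SE 0.33) and CLN1 by 1.45 (SE 0.18), while CLN2 stood at 0.97 (SE 0.24, adjusted p = 0.0674). PUT4 (YOR348C), a proline permease gene, rose by 3.63 (SE 0.53), and YHR214W-A, a subtelomeric reading frame with close relatives, by 3.49 (SE 0.44). MFA1 (-3.57, SE 0.25), TIP1 (-3.23), YGP1 (-2.98), PHO3 (-2.87), SPL2 (-2.74) and MFA2 (-2.63) fell.

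Of the 9 SBF regulon cyclins and regulators, 6 rose and 0 fell, 8 and 0 adjusted over the list alone (median 1.03, adjusted p = 3.11e-24, and 0.00559 with an estimated correlation); YHP1 rose by 1.65 and PCL2 by 0.86. Of the 20 SBF regulon cell wall genes, 10 rose and 0 fell, 14 and 1 adjusted over the list alone (median 0.72, adjusted p = 1.05e-20, and 0.0175 with an estimated correlation), with TOS6 at 2.75, SVS1 at 2.64, CSI2 at 2.16 and MNN1 at 1.61. Of the 32 MBF regulon genes, 5 rose and 1 fell, 8 and 4 adjusted over the list alone: CLB6 rose by 2.32 and NRM1 by 1.95, and CDC21 fell (-1.20). The MBF list's median was -0.18 and its mean 0.15, and the list test, in the higher direction, gave 0.884. With the surrogate variable 9 were called higher and 8 lower.

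Of the mating pheromone response genes AGA1 and AGA2 fell (-1.71 and -1.14), PRM6 passed at 0.106 against 1.37 CPM with a lowest count of 1, and 7 fell and 1 rose adjusted over the list alone (adjusted p = 5.56e-07, and 0.00559 with an estimated correlation). The PHO regulon passed both ways: SPL2, PHO5 at -2.13 and PHO89 at -1.63 fell, 6 fell adjusted over the list alone, and all 14 values were negative (adjusted p = 1.31e-15, and 0.0259 with an estimated correlation). Of the ECB and MCM genes, MCM7 (-1.34) and MCM5 (-0.94) fell, with 6 lower and 1 higher adjusted over the list alone (adjusted p = 1.58e-06, and 0.0608 with an estimated correlation). Of the iron genes, SIT1 (-2.32) and the siderophore transporter gene ARN1 (YHL040C; -1.09) fell, and the cell wall siderophore-retention gene FIT1 (YDR534C) rose by 2.24, with 5 lower and 1 higher adjusted over the list alone (adjusted p = 6.07e-06, and 0.0770 with an estimated correlation).

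Sulfur assimilation genes MET14 (YKL001C) and MET3 (YJR010W) rose by 1.17 and 0.91, and 3 of 17 rose adjusted over the list alone (adjusted p = 3.77e-07, and 0.0770 with an estimated correlation). All 8 core histone values were positive with 0 calls, 2 adjusted over the list alone and a median of 0.59 (adjusted p = 1.34e-06, and 0.158 with an estimated correlation); with the surrogate variable 6 were called higher. The CLB2 cluster had 0 calls and a median of 0.43 (adjusted p = 5.70e-05, and 0.412 with an estimated correlation). Stress genes split: the membrane-protecting HSP12 (YFL014W) rose by 2.95 and YGP1 fell, with 3 higher and 3 lower adjusted over the list alone and a median of 0.30 (adjusted p = 0.0391, and 0.700 with an estimated correlation). CWP1 rose by 2.51 among the Rlm1 genes (2 adjusted over the list alone, list test adjusted p = 0.0388, and 0.417 with an estimated correlation). Its call was lost with RLE size factors, with a mean CPM of at least 10 and with only the groups compared. Gcn4 targets had 0 calls, 2 lower adjusted over the list alone and a median of -0.24 (adjusted p = 5.42e-05, and 0.591 with an estimated correlation). Calls with the surrogate variable were 1 higher and 11 lower for Gcn4 targets, and 11 higher for the CLB2 cluster. Stress genes then had 7 higher and 3 lower. There were 5 higher and 3 lower for the Rlm1 genes, 6 higher for the sulfur genes, and 10 lower for the PHO genes. The pheromone response had 1 higher and 8 lower. Further counts were 1 higher and 6 lower for the ECB and MCM genes, 16 higher and 1 lower for the SBF cell wall genes and 2 higher and 9 lower for the iron genes.

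The other 11 lists did not pass at 4 h. Ribosomal proteins gave 0.0744, galactose genes 0.212, pleiotropic drug response 0.248, ergosterol biosynthesis 0.428, ribosome biogenesis 0.473, alpha-specific genes 0.759 with 3 tested, meiosis and sporulation 0.812 with SPS4 at 1.66 as its called member, MBF genes 0.884, and respiratory chain, glucose-repressed genes and Hcm1 targets 0.953 each. Among these, the median and mean of the Hcm1 and glucose-repressed lists differed in sign and lay within 0.026 of 0. Of the regulators, MSA1 fell (-1.17, adjusted p = 0.0172) and WHI5 stood at -1.20 (0.128), while SWI6, at 0.08, MBP1, at -0.01, CLN3, at -0.11, BCK2, at -0.11, STB1, at -0.04, and MSA2, at 0.03, had adjusted p-values that rounded to 1.

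At 4 h 119 genes were called, 75 higher and 44 lower, 108 of them beyond 2-fold, and 497 had an unadjusted p under 0.05. The count was 43 without ethanol 4 h replicate 1, 44 without ethanol 4 h replicate 2, 49 without estradiol 4 h replicate 1 and 43 without estradiol 4 h replicate 2, and 17 of the 41 named calls were kept whichever library was left out, among them SWI4, CLN1, PCL1, HO, MFA1, MFA2, YGP1, SPL2, SVS1, NRM1 and HSP12. With library totals as the only scaling, 65 were higher and 54 lower, and CLN1 had an adjusted p of 0.188.

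**Figure D2:**
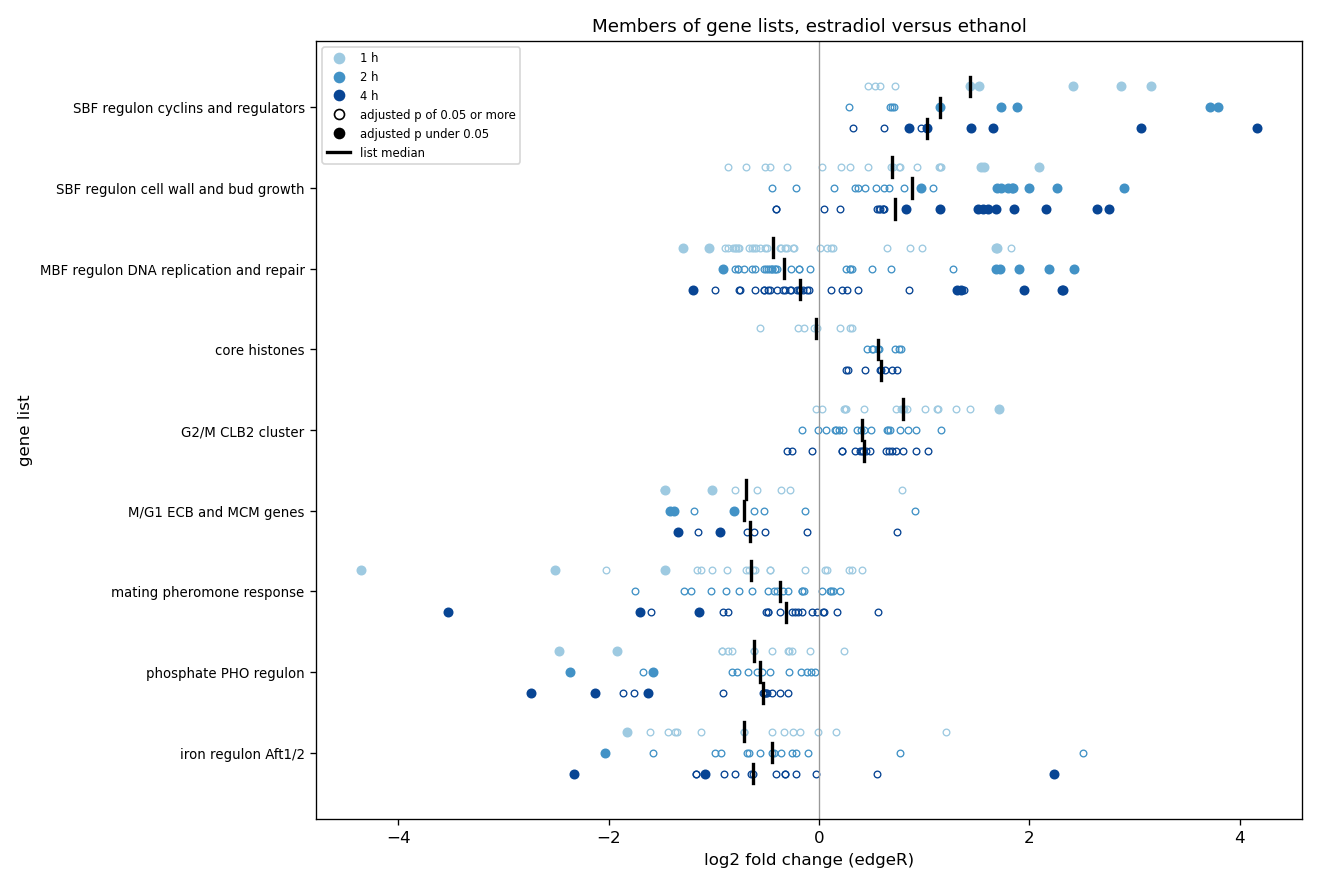
Log2 fold change of estradiol against ethanol for every tested member of 9 gene lists at 1, 2 and 4 h; filled points have an adjusted p under 0.05 and black bars are list medians. The median of the SBF cyclins and regulators was 1.44, 1.15 and 1.03, and that of the ECB and MCM genes -0.69, -0.71 and -0.65.

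**Figure D3:**
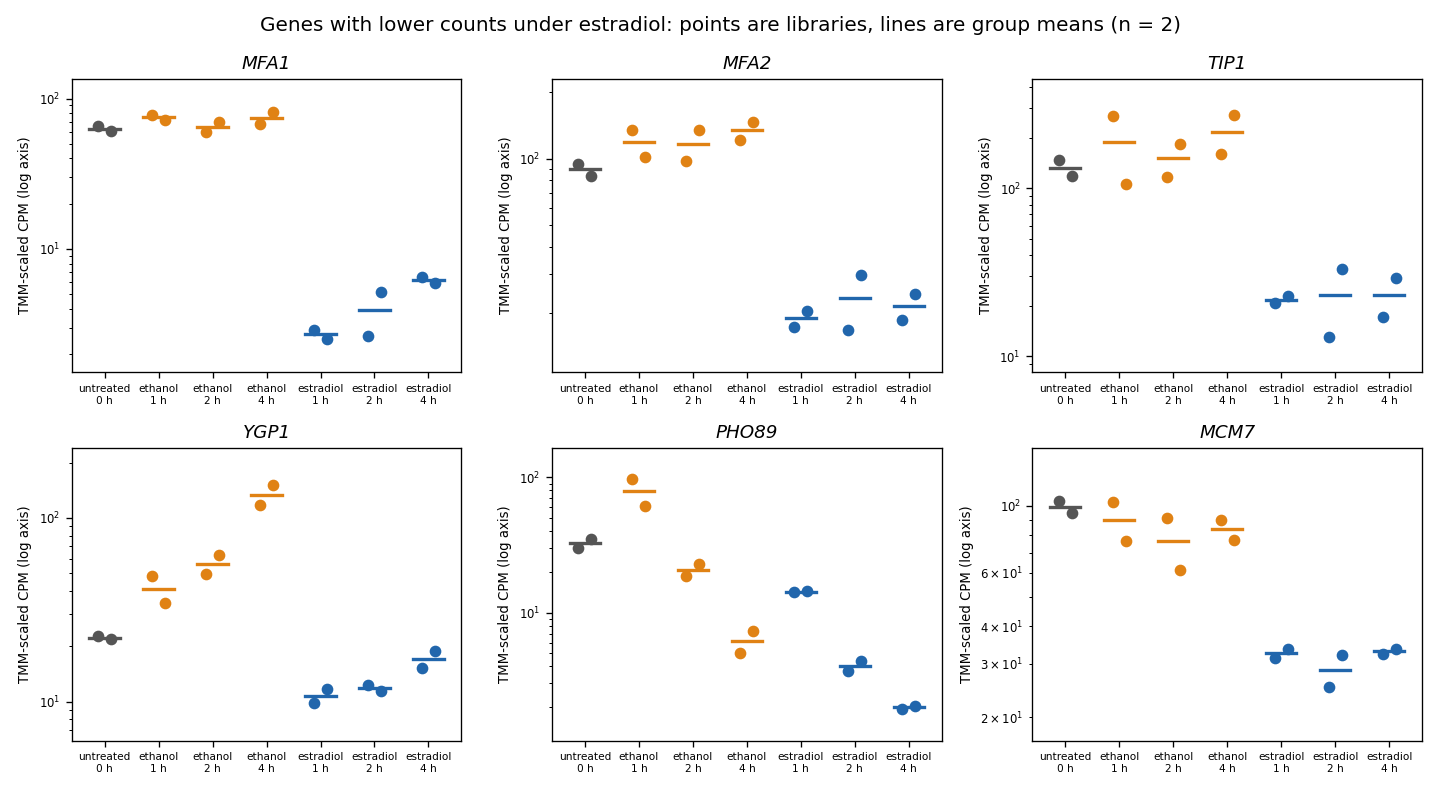
TMM-scaled CPM on a log axis for 6 genes in the 7 groups; each point is a library and each line the mean of a group (n = 2). MFA1 averaged 2.70 to 6.25 CPM in the estradiol groups and 63.2 to 75.0 CPM in the others.

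Across the 3 times, 24 genes were called higher at each, among them SWI4, PCL1, HO, CLN1, YHP1, CSI2, MNN1, TOS6, CLB5, NRM1, RNR2 and URA3 (YEL021W), and 14 were called lower at each, among them MFA1, MFA2, TIP1, PHO3, PHO89, SIT1, YGP1, CDC21, MCM5 and MCM7. URA3, a pyrimidine biosynthesis gene outside the naming rule, was chosen after its values were seen. The 2 h and 4 h calls shared 53 higher and 17 lower genes, against 0.675 and 0.160 expected by chance. The 1 h and 2 h calls shared 26 and 16 (0.270 and 0.113 expected), the 1 h and 4 h calls 25 and 20 (0.355 and 0.215 expected), and 0 genes were called in opposite directions. Over all 6337 genes, the log2 fold changes at 2 h and 4 h had a Pearson correlation of 0.770 and a Spearman correlation of 0.589 across genes, which are not independent replicates. The times share no library, but all calls come from the same fit, with each gene's spread estimated over all libraries. The counts expected by chance take the calls as independent, which they are not.

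Averaged over the times, with 6 libraries against 6, WHI5, the inhibitor of SBF, was called although no single time called it: it fell (-1.25, SE 0.20, adjusted p = 0.00218). MSA1 fell (-1.12, SE 0.13) and CLN2 rose by 1.20 (SE 0.14, adjusted p = 0.000229). SWI6 stood at 0.35 (adjusted p = 0.503) and MBP1 at 0.46 (adjusted p = 0.438). MFA1 fell (-4.08, SE 0.20), and so did the alpha-factor receptor gene STE2 (YFL026W; -0.96, SE 0.14), the latter chosen after its values were seen. The fit for the average takes the libraries as independent of each other. Replicate differences were correlated between the estradiol times (0.79, 0.68 and 0.76 across genes). In ethanol the correlations were -0.42, -0.70 and 0.58. If the times were drawn from the same cultures, which the labels do not say, the p-values of the average could be too small. Of 6320 genes 393 were called, 208 higher and 185 lower, and 147 of them lay beyond 2-fold. The count was 223 without ethanol 2 h replicate 2, 219 without ethanol 4 h replicate 2 and 237 without estradiol 4 h replicate 1.

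For a change of the estradiol effect with time, edgeR called 0 of 6337 genes, with 72 at an unadjusted p under 0.05; DESeq2 called 2. CLN1 effects of 2.41, 1.89 and 1.45 and HO effects of 2.87, 3.79 and 4.17 at 1, 2 and 4 h had unadjusted p-values of 0.00966 and 0.00174 in this test and did not pass over all genes, so no gene was named by the rule. How large a change with time the test can find was not simulated, and 72 genes lie below the 316.85 expected by chance, so the absence of calls is not evidence of equal effects.

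Against untreated cells, the estradiol groups showed SWI4 higher by 6.15 (SE 0.46), 5.90 (SE 0.45) and 5.47 (SE 0.44) at 1, 2 and 4 h (n = 2 each). CLN1 rose by 2.29, 2.17 and 2.02, HO by 2.70, 3.70 and 3.59 and PCL1 by 3.14, 3.49 and 3.12, and MFA1 fell (-4.54, -4.05 and -3.34). These comparisons also hold what time and ethanol go with: HXK1 (YFR053C), a glucose-repressed hexokinase gene, rose by 2.50, 3.97 and 5.80 against untreated cells and stood at 0.01, 0.69 and 0.63 against ethanol. HSP12 rose by 6.25 at 4 h, and PHO89 fell (-1.19, -3.01 and -4.02). YGP1 stood at -0.39 (SE 0.22) at 4 h and did not pass, against 2.59 in ethanol at 4 h.

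At 1 h 97 genes were called against untreated cells, 64 higher and 33 lower, at 2 h 220, 159 higher and 61 lower, and at 4 h 675, 434 higher and 241 lower. The 1 h count was 12 without untreated replicate 1, 26 without untreated replicate 2, 154 without ethanol 1 h replicate 1, 50 without estradiol 1 h replicate 1, 43 without estradiol 1 h replicate 2 and 147 without estradiol 2 h replicate 2. The 2 h count was 77 without untreated replicate 1, 71 without untreated replicate 2 and 120 without estradiol 2 h replicate 2, and the 4 h count 205 without untreated replicate 1, 185 without untreated replicate 2, 409 without estradiol 4 h replicate 1 and 183 without estradiol 4 h replicate 2. With library totals as the only scaling, the median of all genes moved by 0.10 at 1 h and by -0.12 at 2 h, and the calls were 62 higher and 18 lower at 1 h and 288 higher and 89 lower at 4 h. DESeq2 split its calls 131 to 96 at 1 h.

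Ethanol against untreated cells measures what the solvent, the handling and the time in culture go with. At 4 h HXK1 rose by 5.17 (SE 0.42, n = 2, adjusted p = 0.000215), from 6.14 ± 1.04 to 220.1 ± 64.3 CPM, and HXT4 (YHR092C), a glucose transporter gene, by 3.93 (SE 0.45). The glycogen synthase gene GSY2 (YLR258W) rose by 2.09 (SE 0.18) and the glycogen phosphorylase gene GPH1 (YPR160W) by 2.68 (SE 0.35). PHO89 (-2.39, SE 0.26), YOL014W (-1.73), YOR385W (-1.64) and FRE4 (YNR060W; -1.43), a ferric reductase gene, fell. The systematic name of YFR052C-A, at 3.86, places it next to HXK1, and that of YER067C-A, at 3.51, beside RGI1 on the opposite strand; neither has a symbol in the gene table, and neither is treated as a separate gene.

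Of the 22 stress genes 9 rose and 0 fell, 20 and 0 adjusted over the list alone (mean 1.59), with YGP1 at 2.59 and the phosphoglucomutase gene PGM2 (YMR105C) at 1.99. The list test gave 4.93e-22, and an adjusted p of 0.224 with an estimated correlation. Of 41 respiratory chain and TCA cycle genes 7 rose, 29 adjusted over the list alone, and all 41 values were positive (median 0.67, adjusted p = 4.93e-22, and 0.268 with an estimated correlation); the citrate synthase gene CIT1 (YNR001C) rose by 1.48, QCR10 (YHR001W-A) by 1.28, CYT1 (YOR065W) by 0.94 and QCR9 (YGR183C) by 0.93. Of 20 glucose-repressed genes 3 rose, 6 adjusted over the list alone: HXK1 and the near-identical hexose transporter genes HXT7 (YDR342C) and HXT6 (YDR343C), at 3.29 and 3.11, whose reads are hard to assign (adjusted p = 2.72e-07, and 0.411 with an estimated correlation). MTH1 (YDR277C), a regulator of glucose transporter genes, rose by 1.49 in the galactose list (adjusted p = 0.103).

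Of 33 ribosome biogenesis genes NHP2 (YDL208W) fell (-0.95), 26 fell adjusted over the list alone and all 33 values were negative (median -0.76, adjusted p = 1.29e-18, and 0.268 with an estimated correlation). Of 132 ribosomal protein genes RPS28B (YLR264W) fell (-1.15), with a median of -0.19 (adjusted p = 2.29e-05, and 0.742 with an estimated correlation). The calls of NHP2 and RPS28B were each lost without either untreated library. PHO genes (median -0.34, adjusted p = 0.00826, and 0.714 with an estimated correlation), Rlm1 genes (median 0.58, 5 higher adjusted over the list alone, adjusted p = 0.0123, and 0.615 with an estimated correlation), Gcn4 targets (median 0.20, but -0.01 with the surrogate variable and -0.05 without the GC trend, adjusted p = 0.0175, and 0.745 with an estimated correlation) and the CLB2 cluster (median -0.34, adjusted p = 0.0374, and 0.714 with an estimated correlation) also passed. With the surrogate variable 7 of the 9 lists that passed still did, not the Gcn4 targets or the CLB2 cluster, whose median was then -0.091, and the Rlm1 median was 0.27. With it 61 of 132 ribosomal protein genes were called lower, at a median of -0.38, and 30 of 33 ribosome biogenesis genes, at a median of -0.67. The counts were 20 higher for stress genes, 31 for respiratory genes and 6 for glucose-repressed genes. Gcn4 targets had 8 higher and 2 lower, and PHO genes 1 higher and 9 lower. There were 5 higher for Rlm1 genes, 1 higher for the CLB2 cluster and 4 higher and 1 lower for the SBF cyclins and regulators. The SBF cyclins and regulators had 0 calls and a median of 0.19 (adjusted p = 0.183).

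**Figure D4:**
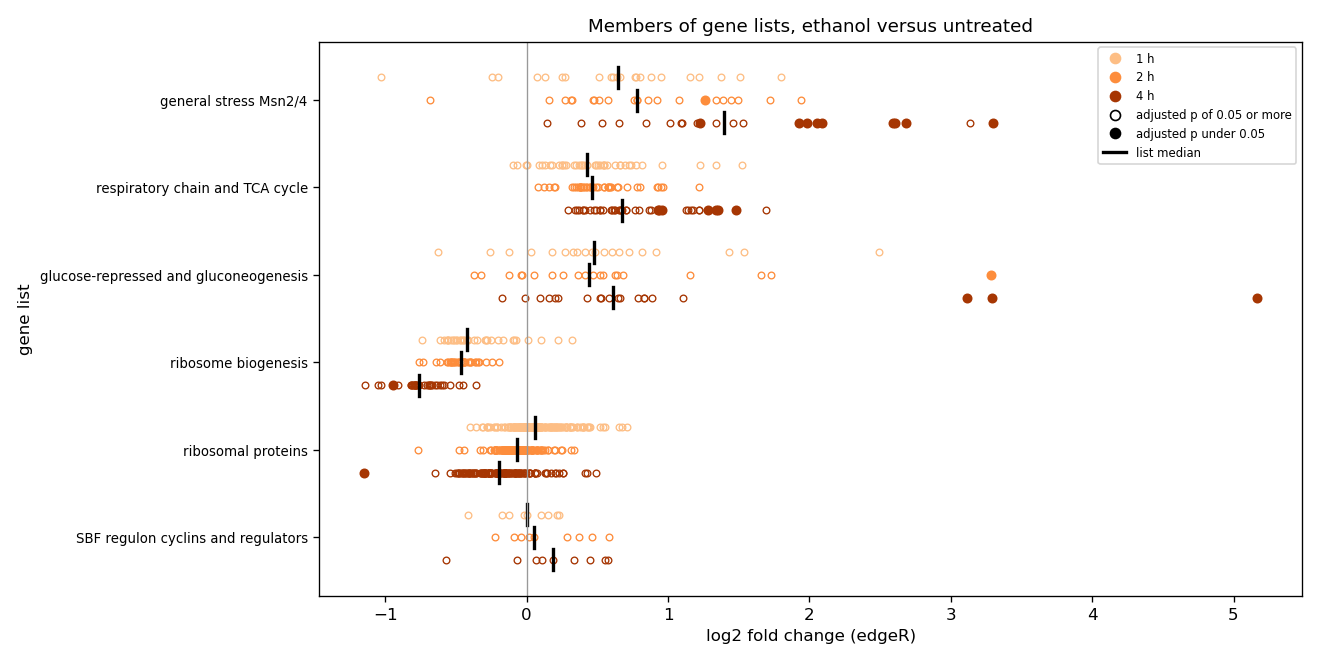
Log2 fold change of ethanol against untreated cells for every tested member of 6 gene lists at 1, 2 and 4 h; filled points have an adjusted p under 0.05 and black bars are list medians. The median of the stress genes was 0.65 and 0.78 at 1 and 2 h, and at 1, 2 and 4 h that of the ribosome biogenesis genes was -0.42, -0.46 and -0.76.

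In all, 110 genes were called in ethanol at 4 h, 92 higher and 18 lower, with 1097 at an unadjusted p under 0.05. The count was 14 without untreated replicate 1, 10 without untreated replicate 2, 71 without ethanol 4 h replicate 1, 26 without ethanol 4 h replicate 2, 216 without estradiol 2 h replicate 1 and 215 without estradiol 2 h replicate 2; HXK1, GSY2, YGP1, PHO89 and YOL014W were among 7 of the 21 named calls kept whichever library was left out. With library totals as the only scaling 90 were higher and 4 lower, and DESeq2 called 302 higher and 184 lower. At 2 h 3 genes were called, HXK1 (3.28, SE 0.40), GSY2 (1.26, SE 0.18) and YBR032W (2.08, SE 0.30), the last named after its values were seen; 374 had an unadjusted p under 0.05 and DESeq2 called 41. That count fell to 0 without either untreated library, either ethanol 1 h library or either ethanol 2 h library, and to 1 without either ethanol 4 h library, either estradiol 1 h library or estradiol 2 h replicate 2. At 1 h edgeR called 0 genes, with 397 at an unadjusted p under 0.05, and DESeq2 called 22; without estradiol 2 h replicate 1 or replicate 2 edgeR called 2, and library totals alone moved the median of all genes by -0.21.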

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

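The list test on the change of the estradiol effect with time passed for 12 lists for the 2 h effect minus the 1 h effect. For the 4 h effect minus the 1 h effect it passed for 10 lists. The main edgeR fit called no gene for either difference. The SBF regulon cell wall and bud growth genes gained 0.64 in the median from 1 h to 2 h (adjusted p = 0.000242), core histones 0.57 (adjusted p = 1.95e-05) and sulfur and methionine genes 0.59 (adjusted p = 0.000269). With an estimated correlation 0 and 0 lists passed, and the SBF cell wall genes had an adjusted p of 0.486. Without ethanol 1 h replicate 1 the counts were 9 and 6, and with the surrogate variable 11 and 10. The list test on differences between times was added after the data were seen, so these counts are given without further use.

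Libraries of the same group differed along a single shared direction, which held 67.0% of the variance within groups over 6325 genes. Its weight on genes followed GC content, with a Spearman correlation of -0.61 across genes. After the GC trend was removed from each library, the leading direction was computed anew. It held 64.2% as much variance as the leading direction before removal. The calls at 1, 2 and 4 h were 274, 408 and 649 with a surrogate variable estimated from the same counts. The share of counts from reading frames inside the ribosomal DNA ran from 1.94% to 8.81% of a library.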

How the results depend on the processing

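The estradiol calls against ethanol, 61, 80 and 119 at 1, 2 and 4 h, kept SWI4, CLN1, PCL1, HO, MFA1 and MFA2 without any 1 library, while the number of calls moved. With DESeq2 it was 157, 150 and 208, with the surrogate variable 274, 408 and 649, and without the GC trend 125, 139 and 213; with only the groups compared it was 97 at 1 h and 40 at 2 h. The 80 calls at 2 h and the 119 at 4 h all remained with DESeq2, and 60 of 61 at 1 h. Against untreated cells, the estradiol calls of 97, 220 and 675 became 227, 444 and 1133 with DESeq2, 990, 1411 and 2390 with the surrogate variable, 209, 366 and 1174 without the GC trend, and 271, 41 and 1855 with only the groups compared; at 4 h library totals gave 377. The ethanol calls of 0, 3 and 110 became 22, 41 and 486 with DESeq2, 31, 161 and 1273 with the surrogate variable and 3, 13 and 335 without the GC trend. With only the groups compared they were 255 at 2 h and 853 at 4 h, with the replicate number as a block 5 and 175, at 1 h with library totals 1, and at 2 h without the length trend 1. Over 21 pairs of groups the correlation of replicate differences was over 0.1 in 11 and under -0.1 in 10. It was 0.43 to 0.82 in the 10 pairs among ethanol 2 h and 4 h and estradiol 1, 2 and 4 h, 0.75 between untreated and ethanol 1 h, and negative in the 10 pairs across these sets, so replicate differences follow the number in 5 groups and run opposite in 2. The average over the times, 393, was 1236 with the surrogate variable, and the change with time, 0, was 2 with DESeq2 and 16 with the surrogate variable. Lists past the test, 12, 13 and 13 at 1, 2 and 4 h and 9 for ethanol at 4 h, were 3, 4, 5 and 0 with an estimated correlation, and 4, 4, 6 and 0 with the surrogate variable besides. Leaving out each library gave 12 to 205 calls at 1 h, 29 to 95 at 2 h and 43 to 159 at 4 h; against untreated cells 12 to 154, 71 to 294 and 183 to 919 for estradiol and 0 to 2, 0 to 4 and 10 to 216 for ethanol; 219 to 445 for the average and 0 to 0 for the change with time. Leaving out each of the 4 libraries of the groups compared gave 11 to 13, 11 to 14 and 12 to 16 lists at 1, 2 and 4 h. Of the 36, 33 and 41 named calls, 15, 9 and 11 were lost with library totals. Ribosomal proteins at 1 h turned with the surrogate variable (adjusted p = 0.259, and 0.821 with an estimated correlation), as did ergosterol biosynthesis (0.604 and 0.821), which also turned without ethanol 1 h replicate 1 (0.741) and without replicate 2 had 5.89e-05. At 2 h Gcn4 targets turned without estradiol 2 h replicate 1 (0.554; 7.39e-08 without replicate 2) and general stress genes without estradiol 2 h replicate 2 (0.871; 0.00205 without replicate 1). For each of these moves the cause was not tested.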

Other observations

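Genes of this paragraph outside the naming rule were chosen after their values were seen. RNR2 and RNR1 rose at 2 h and 4 h, while the other subunit genes of ribonucleotide reductase did not pass at 4 h: RNR4 (YGR180C) stood at 1.17 (adjusted p = 0.431) and RNR3 (YIL066C), which DNA damage induces, at 0.14. The subtelomeric reading frames YAR068W, YHR214W and YAR066W rose at 4 h by 3.47, 2.98 and 2.81; they were picked for their values, and reads of such relatives are hard to assign to a single member. The cell wall mannoprotein genes TIR1 and CWP1 rose at 4 h by 3.08 and 2.51, against -3.23 for TIP1. The call of CWP1 was lost with RLE size factors and with only the groups compared.

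For the a-specific genes the tests on alpha-specific genes and at 1 h were chosen only after the result was seen. MFA1, MFA2, AGA2 and STE2, which only a cells express, were lower on average over the times while HO was higher. A switch of mating type through HO could lower these genes. The medians of a-specific genes below are over a list that is not these genes alone. At 1 h and 4 h they are smaller in size than the values of MFA1, MFA2 and AGA2. The 3 tested alpha-specific genes, which a switch to alpha would raise, had a median of -0.15 at 4 h. The surrogate variable differed between the groups at 1 h and moved the fold changes of all genes there by 0.231 in the median. With it the median of the a-specific genes at 1 h went from -1.16 to -0.92, which argues against the direction shared by libraries of a group as the whole cause at 1 h. At 4 h the median was -0.88 with it, but the variable hardly differed between the groups (by 0.0201), so that test decides nothing. Whether the cells can switch is not known from the labels.

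For URA3 the tests on the pyrimidine pathway and at 1 h were chosen only after the result was seen. URA3 rose by 1.78 (SE 0.27) at 4 h, and the other pyrimidine genes had a median of -0.045. Its neighbours GEA2 (YEL022W) and TIM9 (YEL020W-A) had a median of -0.20, which leaves no sign of a rise shared along the chromosome at the reference locus. These neighbours do not bear on a copy of URA3 placed elsewhere. URA3 with the surrogate variable went from 1.85 to 1.67 (SE 0.21) at 1 h, which argues against the shared direction as the whole cause at that time. At 4 h URA3 was at 1.78 with it, but the variable hardly differed between the groups there, so that test decides nothing. A URA3 marker beside the induced promoter could give such a rise, but the labels name no marker and this was not tested.

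For the spread within groups the tests on gene length, replicate number and ribosomal DNA were chosen only after the result was seen, and the ribosomal DNA set was widened from 7 to 12 reading frames after its first result, with the same outcome. The weight of genes on the shared direction had a Spearman correlation of -0.61 with GC content and 0.27 with length across genes. The leading direction computed anew after removal of the GC trend held 64.2% as much variance. Replicate 1 lay on the same side in 5 of 7 groups, where a batch named by the replicate number would give all 7. Replicate 2 had the larger total count in every group, so the library total also gave 5 of 7. Replicate number and depth cannot be told apart here. Replicate differences were correlated between groups, so the groups are not independent. The library with more ribosomal DNA counts lay on the same side in 7 of 7 groups (exact sign probability 0.0156 under independence). A difference in library preparation that favours GC content and ribosomal RNA is consistent with both; both are properties of the same libraries, so neither is set above the other.

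Of 100 splits of the 12 treated libraries, the real grouping included, 1 gave as many calls as the 393 of the real grouping, namely itself, and the highest other gave 384. That split kept 5 of 6 estradiol libraries together, but 5 more splits that did so gave 0 calls each, and what sets it apart was not tested. Most splits mixed estradiol and ethanol libraries on each side, so large effects such as that of SWI4 entered the spread. Few calls were therefore likely in those splits, and their count alone does not exclude chance.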
